A study of Mus musculus with 2 samples.

How the data were processed

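Nuclei of the cervical spinal cord of mice at postnatal day 25 were profiled by droplet single-nucleus RNA sequencing with the 10x Genomics v3.1 chemistry, which reads the 3′ end of each captured RNA. The control library came from animals with a Cre insertion in 1 copy of Ptf1a, a null allele, and a wild-type second copy. In the mutant library the second copy carried a mutation of a Ptf1a enhancer, called AR-DNT1 in the labels. Both genotypes also carried Ai14, a tdTomato reporter of Cre activity, whose transcripts were not found according to the labels, so nuclei of the Ptf1a lineage could not be picked out by it. There was 1 library per genotype, each pooling 2 animals.

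The deposited matrices of both libraries hold raw counts of unique molecular identifiers (UMIs) per gene and barcode. They were made with Cell Ranger 3.1.0 against mm10, per the submitters' processing notes. How barcodes were chosen is not given in the sources used here. The authors' deposited table of average expression holds a linear signal per neuron cluster, and each of its 31 columns was found to sum to 10000.0. Seurat 3.1.1 is named in the submitters' processing notes. Which nuclei each column averages is not given in the sources used here. Whether the counting used strand is not stated either, so Ptf1a and the overlapping antisense gene Ptf1aos were read together. Gene coordinates are those of the GENCODE annotation of mm10.

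Nuclei were kept with at least 500 detected genes, at most 5.0% mitochondrial UMIs and no doublet call by Scrublet, run per library in scanpy 1.11.5 with an expected doublet rate of 0.08. The score thresholds it set were 0.272 in the control and 0.261 in the mutant library. Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours entered Leiden clustering (leidenalg 0.10.2) at resolution 1.0, on both libraries jointly and without integration. Of the 33 clusters of nuclei, neuron clusters were clustered again with the same settings. Clusters were named from 16 marker lists of 197 genes fixed before the data were examined, so a class name stands for nuclei that resemble that type by those markers. A cluster needed at least 3 detected markers, a best mean log2 enrichment of at least 0.3 and no unrelated list above 0.3. The exact scoring was set with the data at hand.

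Of the 29 neuron clusters, 4 in which a glial list scored above 1.0 were set aside as mixed (214 control and 247 mutant nuclei) and joined the unnamed nuclei. Among them, cluster 24 (54 control and 39 mutant nuclei) scored highest on the cholinergic list, with Slc5a7 and Chodl among its leading genes. A neuron cluster was called inhibitory where the mean of Gad1, Gad2, Slc32a1 and Slc6a5 exceeded Slc17a6 by more than 1.0 on the log2 scale, and excitatory in the opposite case. A cluster between these bounds, cluster 3, was left unresolved. Cluster 18 was kept out of the excitatory class because markers of other classes outnumbered excitatory markers among its leading genes. The 25 remaining clusters hold 7 inhibitory and 14 excitatory ones.

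Because each genotype is represented by 1 library, no test was made and no p-value is given. UMI sums per class and library are given as CPM of that sum, shares of nuclei as percentages, and each ratio is mutant over control. Bracketed ranges are exact 95% intervals, Poisson for sums, Clopper-Pearson for shares and conditional binomial for ratios, and cover counting error only, not the spread between animals. A count of 0 is given with the level that 3 counts would make. To compare shares of nuclei with a UMI of a gene, each nucleus was thinned to 1000 UMIs, with shallower nuclei left out, and oligodendrocytes served as background for free RNA. For neurons, 19 gene lists with 250 genes were fixed before the data were examined. For each list, the median log2 ratio of members with at least 50 UMIs is given with its percentile among 10000 random lists of the same size matched on expression, which describes these libraries only.

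The genes named were chosen by a rule fixed before the data were examined. In each neuron class, genes with at least 100 UMIs whose ratio interval excluded 1 were ranked by the bound nearest to 1, and the 10 highest and 10 lowest were taken. In each glial class the 3 highest and 3 lowest were taken. The ranking left out sex-linked and mitochondrial genes, and members of the fixed lists could be named at any value. The neuron clusters named were the 3 with the largest and the 3 with the smallest share ratio among those with at least 50 nuclei, and every inhibitory cluster with a ratio above 1.5 or below 0.67. The same rule applied to all nuclei together, and the lists of glucocorticoid-induced, neutrophil and Schwann cell genes, were added after the data had been seen.

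The sums and intervals were tested on simulated counts for 16351 genes of the comparison of summed UMIs, 200 of them altered. The 95% intervals held the true ratio for 95.4% of genes, and 4.65% of unaltered genes had an interval excluding 1. Intervals excluded 1 for 100.0% of genes altered 2-fold and 84.0% of those altered 1.25-fold. A lowered list of 15 genes lay at percentile 0, and 5.0% of 200 random lists lay outside the central 95% range. The simulated counts were independent Poisson draws, so these values check the calculation only. They held no UMIs clumped in single nuclei, no differences between animals and no genes that vary together.

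Alternatives covered filters on genes and mitochondrial UMIs, doublets kept, other clustering settings, components centred per library, marker genes left out of the variable genes, nuclei called one by one, other thinning depths, other scalings with TMM factors (edgeR 4.0.16 in R 4.3.3), sums thinned to 1000 UMIs, and clusters weighted equally. After the data had been seen, sums over nuclei with an Xist UMI and no Y-linked UMI, a separate clustering of the unresolved neurons, nuclei called one by one from at least 2 UMIs and cluster shares without marker genes were added. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9 were used.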

Results

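Single-nucleus RNA sequencing of mouse cervical spinal cord at postnatal day 25 gave 11342 barcodes with 61541015 UMIs in the control library and 11824 barcodes with 58381909 UMIs in the mutant library. After filtering, 9578 control nuclei with a median of 4216 UMIs and 10142 mutant nuclei with a median of 3599 UMIs remained. Mitochondrial UMIs exceeded the limit in 12.1% of control and 7.90% of mutant barcodes, and doublet calls removed 447 control and 649 mutant barcodes. Each library pooled 2 animals and stood alone for its genotype, so every difference below is between libraries, without a replicate check.

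The libraries also differed in sex-linked transcripts. Eif2s3y, a Y-linked gene, had 114 CPM in the control and 0.0793 CPM (4 UMIs) in the mutant library, and Uty had 110.0 and 2.14 CPM. Xist, expressed from the inactive X chromosome, had 857 CPM in the control and 1605 CPM in the mutant library, and Tsix had 30.4 and 78.4 CPM. Of the control nuclei, 3885 (40.6%) held an Xist UMI and no Y-linked UMI and 3502 (36.6%) the reverse, against 9094 (89.7%) and 21 (0.207%) of the mutant nuclei. Genotype and the sex mix of the pooled animals therefore differ together, and values within Xist-only nuclei are set beside the main ones where they bear on a result.

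The targeted gene itself was at the limit of detection. Ptf1a encodes a basic helix-loop-helix factor that directs dorsal spinal progenitors to inhibitory fates in the embryo (ENSMUSG00000026735, mm10 chromosome 2, 19445663 to 19447501, plus strand, 2 exons). It had 0 UMIs in the control library, which allows up to 0.0488 CPM, and 1 UMI in the mutant library. The antisense gene Ptf1aos, on the minus strand at 19441508 to 19446674, also had 0 and 1 UMIs. In the authors' deposited table Ptf1a is listed at 0 in all 31 neuron clusters. Ptf1a RNA at this age can therefore not check the genotype labels. The neighbouring genes were at like levels in neurons of both libraries. Msrb2, a methionine sulfoxide reductase at 19371440 to 19394976, had 14.6 CPM in each (ratio 0.996 [0.871 to 1.14]), Otud1 had a ratio of 0.896 [0.531 to 1.5] and Armc3 1.05 [0.830 to 1.31]. The list of the targeted gene and its neighbours had a median log2 ratio of -0.01 over 3 measured members, at percentile 49.2 of random lists.

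Cell class shares, the first comparison, were alike in the libraries for most of the tissue. Neurons made up 38.3% [37.3 to 39.3] of control and 38.8% [37.8 to 39.7] of mutant nuclei, and oligodendrocytes 33.6% and 34.0%. Oligodendrocyte nuclei sat in different clusters, since cluster 4 held 1080 control and 383 mutant nuclei and cluster 0 held 1018 and 1790, so the class differs in makeup. Astrocytes were more frequent in the mutant library, at 8.15% [7.63 to 8.70] against 6.38% [5.90 to 6.89], a ratio of 1.28 [1.15 to 1.42]. Their makeup differed too, since astrocyte cluster 22, led by Myoc and A2m, held 33 control and 90 mutant nuclei. Meningeal fibroblasts, the collagen-producing cells of the spinal coverings, numbered 114 in the control and 13 in the mutant library, which is 1.19% [0.983 to 1.43] and 0.128% [0.0683 to 0.219]. Within nuclei holding only Xist, the fibroblast share was 0.129% in the control and 0.143% in the mutant library, a ratio of 1.11, so the direction turned there. Oligodendrocyte precursors (3.73% and 3.83%), committed oligodendrocyte precursors (2.42% and 2.62%), microglia (3.47% and 3.29%) and endothelial cells (0.595% and 0.542%) had ratios whose intervals held 1. Mural cells (19 and 28 nuclei) and macrophages (9 and 16) were few. Unnamed nuclei, 10.0% of the control and 8.19% of the mutant library, were shallow, with median UMIs of 938 and 1120.

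Inhibitory neurons, the cells whose specification the study addresses, took a smaller share of neurons in the mutant library. They were 33.9% [32.4 to 35.5] of 3666 control neurons and 19.5% [18.3 to 20.8] of 3933 mutant neurons, a ratio of 0.575 [0.525 to 0.630]. Excitatory neurons were 57.1% [55.5 to 58.8] and 65.9% [64.5 to 67.4], a ratio of 1.15 [1.09 to 1.22]. The control library held 0.593 inhibitory neurons per excitatory neuron and the mutant library 0.296, a ratio of 0.498 [0.447 to 0.555]. The unresolved cluster 3, outside both classes, held 5.65% and 10.3% of neurons (ratio 1.83 [1.55 to 2.18]), and the kept-out cluster 18, led by Pdyn and Pou4f1, held 1.88% and 2.26%. Cholinergic neurons were 0.982% and 1.32% and CSF-contacting neurons 0.436% and 0.610%, with intervals of the ratio that held 1. The cholinergic share rests on cluster 25 alone. It leaves out the mixed cluster 24, with 54 control and 39 mutant nuclei, whose best list was cholinergic.

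**Figure D1:**
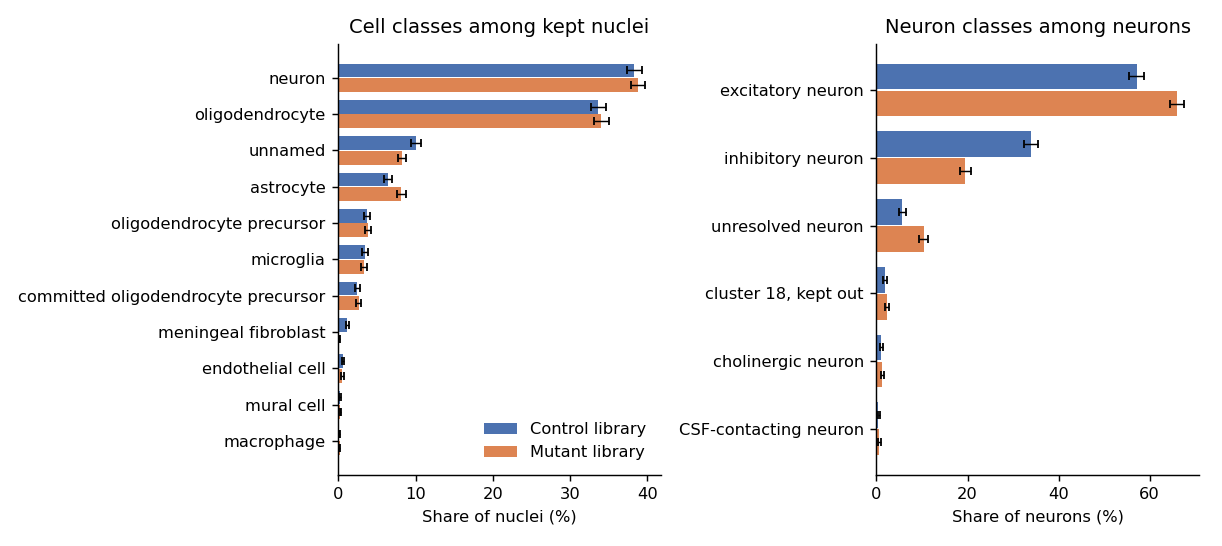
Bars give the share of kept nuclei in each cell class (left, percent) and the share of neurons in each neuron class (right, percent) for the control and mutant libraries, with exact 95% counting intervals. Inhibitory neurons were 33.9% of control and 19.5% of mutant neurons, and meningeal fibroblasts 1.19% and 0.128% of nuclei.

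Neurons were also called inhibitory or excitatory one by one, among the nuclei that the joint clustering had named neurons. With neurons thinned to 1000 UMIs and called one by one from Gad1, Gad2, Slc32a1 and Slc6a5 against Slc17a6, 22.9% [21.6 to 24.4] of control and 15.6% [14.4 to 16.7] of mutant neurons were inhibitory. Excitatory calls were 14.9% and 16.7%, and the inhibitory to excitatory ratio was 1.54 in the control and 0.933 in the mutant library, a ratio of 0.605 [0.517 to 0.707]. Free RNA enters such calls. Among oligodendrocytes, which should lack these genes, 11% of control and 7.91% of mutant nuclei were called inhibitory and 2.58% and 2.82% excitatory, a ratio of inhibitory to excitatory calls of 0.657 [0.465 to 0.930]. Asking for at least 2 UMIs, 8.02% and 4.66% of neurons were inhibitory (oligodendrocytes 0.933% and 0.552%) and 2.02% and 3.0% excitatory (0.0622% and 0.174%), a ratio of 0.390 [0.272 to 0.559]. Median UMIs were 3563 and 2992 in oligodendrocytes against 8149 and 7864 in inhibitory and 6062 and 5131 in excitatory neurons. With marker genes left out of the variable genes, more neurons became unresolved and the inhibitory share ratio was 0.366. In nuclei holding only Xist, inhibitory neurons were 32.1% [29.9 to 34.3] of control and 19.2% [17.9 to 20.5] of mutant neurons, and in control nuclei holding only Y-linked UMIs they were 36.0% [33.5 to 38.6].

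The difference was concentrated in 6 of the 7 inhibitory clusters, which together held 17.3% [16.1 to 18.6] of control and 6.23% [5.49 to 7.03] of mutant neurons, a ratio of 0.359 [0.309 to 0.417]. These 6 were grouped because each had a share ratio below 0.67, so their joint ratio is low by that choice, which its interval does not cover. Cluster 23, led by the neuropeptide genes Gal and Pdyn, held 85 control and 20 mutant nuclei, a share ratio of 0.219 [0.128 to 0.360]. Cluster 26, led by the relaxin-family receptor gene Rxfp2 and the carbonic anhydrase gene Car4, held 58 and 17 nuclei (0.273 [0.149 to 0.476]). Cluster 13, with Adamts5, Nox4 and Gbx1, held 137 and 52 (0.354 [0.252 to 0.490]), and cluster 8, with the nuclear receptor gene Rorb and Sall3, held 176 and 68 (0.360 [0.268 to 0.479]). Cluster 20, led by the cadherin gene Cdh3, had a ratio of 0.417 [0.277 to 0.618], and cluster 19, led by the neuropeptide gene Npy, 0.491 [0.341 to 0.698]. Clustered without the marker genes, the share ratio of the clusters matched to these by shared nuclei was 0.354.

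The largest inhibitory cluster, cluster 1, was led by Slc6a5, the glycine transporter of glycinergic terminals, and held 607 control and 522 mutant nuclei, with a share ratio of 0.802 [0.712 to 0.903]. This value depended on the clustering. Without marker genes, the 2 clusters whose nuclei came most often from cluster 1 held 445 control and 673 mutant nuclei, a ratio of 1.41. They are not the same set of nuclei as cluster 1. At the other end, the unresolved cluster 3 had the largest ratio, followed by cluster 21, an excitatory cluster led by Chst9 and Bnc2 (1.44 [0.979 to 2.13]), and the cholinergic cluster 25, led by Chat (1.35 [0.864 to 2.12]). The 14 excitatory clusters lay between 0.836 and 1.44, so no excitatory cluster was lowered as the 6 inhibitory ones were. Clustered on its own, cluster 3 split into parts. A part with 95 control and 165 mutant nuclei was excitatory, and inhibitory parts held 49 and 78 (led by Pax2 and Foxp2), 22 and 98, and 22 and 48 nuclei. These 4 parts were more frequent in the mutant library, the one of 22 and 98 nuclei with a share ratio of 4.15 [2.60 to 6.93]. Of 2 small parts, one held 15 and 9 nuclei (0.559) and the other 4 and 9 (2.10). With these parts counted in the class each was called, the share ratio of inhibitory neurons was 0.696, and that of inhibitory to excitatory neurons 0.594.

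**Figure D2:**
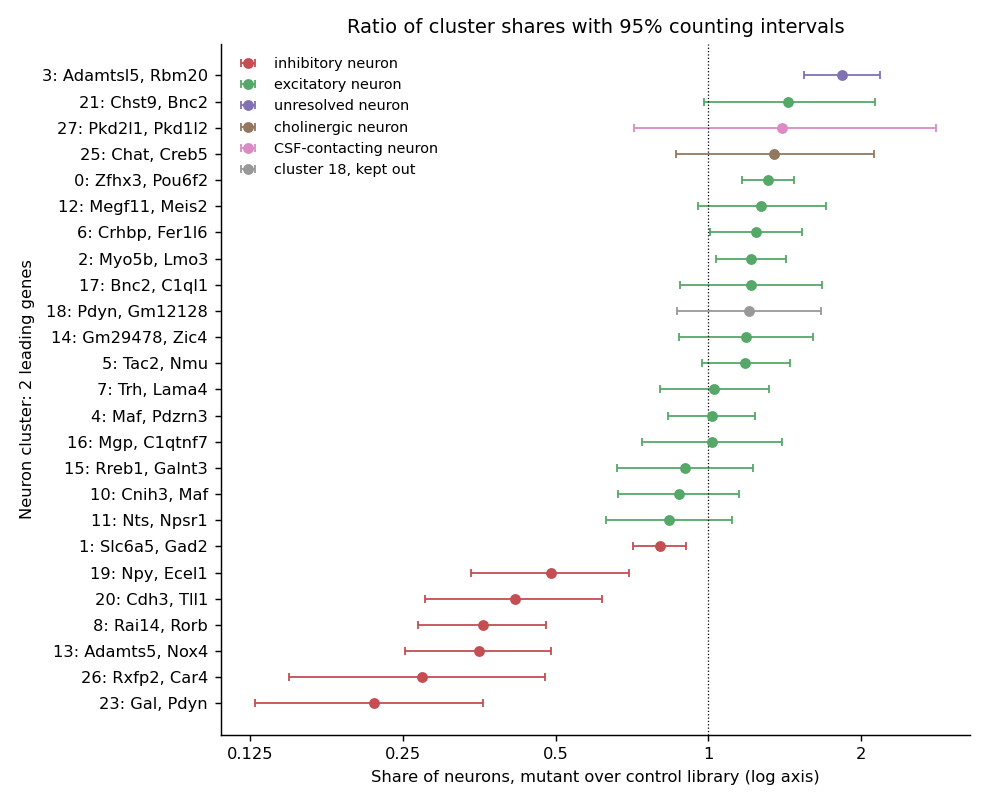
Points give the mutant over control ratio of each neuron cluster's share of neurons on a log axis, with exact 95% counting intervals and colours for the class, and each cluster is labelled by its 2 leading genes. The 6 clusters at the low end are inhibitory, from 0.219 (Gal, Pdyn) to 0.491 (Npy), and excitatory clusters lie between 0.836 and 1.44.

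The authors' deposited table gives average expression in 31 neuron clusters, without numbers of nuclei. By the same rule on inhibitory genes and Slc17a6, 10 clusters of the authors' deposited table were inhibitory, 20 excitatory and 1 neither. Each of the 6 lowered clusters had a close counterpart. Across 394 genes, which are not independent replicates, cluster 23 correlated at 0.988 with cluster 22 of the authors' deposited table, where Gal reached its highest average, 6.66 per 10000. Cluster 19 correlated at 0.962 with the cluster of the authors' deposited table that is highest in Npy (14.9 per 10000). Clusters 8 and 26 correlated at 0.976 and 0.996 with the pair of clusters of the authors' deposited table highest in Rorb (14.1 and 11.4 per 10000). Clusters 20 and 13 had correlations of 0.979 and 0.925 with clusters of the authors' deposited table with Cdh3 at 2.46 and Sall3 at 1.79 per 10000. A high correlation does not single out a well-defined cluster, since the unresolved cluster 3 reached 0.95 with cluster 7 of that table. The authors' table belongs to the same study, so these matches are no independent support.

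Transcription factors of the Ptf1a lineage were lower over all neurons of the mutant library. Of 14 measured members of this list, 11 had a ratio below 1, 9 of them with an interval below 1, with a median log2 ratio of -0.62, below all 10000 random lists. Sall3, a zinc finger factor of the Ptf1a lineage, had 23.4 CPM in the control and 9.29 CPM in the mutant library (0.397 [0.344 to 0.457]). Pax8 had 23.9 and 10.7 CPM (0.449 [0.392 to 0.513]), and Pax2, which marks dorsal inhibitory neurons, 53.6 and 35.5 CPM (0.662 [0.612 to 0.716]). Lhx5 had a ratio of 0.513 [0.401 to 0.651], while Lhx1 had 1.02 [0.865 to 1.20] and Rbpj, the Notch pathway factor that partners PTF1A, 1.13 [1.04 to 1.22]. With each neuron cluster weighted equally, which takes cluster shares out, the median was -0.14. In oligodendrocytes 6 measured members had a median of -0.64, with Sall3, likely free RNA there, at 3.53 and 1.04 CPM, while Rbpj (75.9 CPM in the control) and Rbpjl (13.8 CPM) stood higher than in neurons (36.6 and 0.749 CPM).

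The GABA and glycine machinery was likewise lower over all neurons, in 7 of 7 members (5 with an interval below 1), with a median log2 ratio of -0.63 and a percentile of 0. Slc32a1, the vesicular transporter of both transmitters, had 121 and 72.1 CPM (0.594 [0.563 to 0.627]), the GABA-synthesising enzyme gene Gad1 42.4 and 26.2 CPM (0.618 [0.565 to 0.676]) and the GABA transporter gene Slc6a1 95.7 and 53.5 CPM (0.559 [0.526 to 0.595]). The glycine transporter gene Slc6a5 was closer to 1, at 0.831 [0.796 to 0.867]. Equal weight of clusters gave a median of -0.32. Outside neurons the list had medians of -0.34 in oligodendrocytes, -0.55 in astrocytes, -0.53 in microglia and 0.24 in oligodendrocyte precursors. Glia transcribe some members themselves, with Slc6a1 at 715 CPM in control astrocytes and at 102 and 159 CPM in oligodendrocytes, while Gad1, likely free RNA there, had 24.9 and 11.7 CPM in oligodendrocytes. The median was -0.48 in excitatory and -0.21 in inhibitory neurons. The glutamate machinery had a median of 0.01 over 4 members, with 2 lower.

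Ventral and intermediate transcription factors went the other way, with a ratio above 1 in 14 of 15 measured members over neurons, 7 with an interval above 1 and 8 with one that held 1, a median log2 ratio of 0.33 and a percentile of 99.95. Foxp2, a forkhead factor of ventral interneurons, had 44.1 and 58.1 CPM (1.32 [1.23 to 1.42]) and Zfhx3 111 and 138 CPM (1.23 [1.18 to 1.29]). En1, the V1 interneuron factor, had 34 and 53 UMIs (1.63 [1.04 to 2.58]), and Vsx2, the V2a factor, 23 and 40 (1.82 [1.06 to 3.18]). Pou6f2 was at 0.966 [0.893 to 1.04]. Dorsal excitatory transcription factors had a ratio below 1 in 11 of 15 members, with 8 intervals below and 3 above 1, and a median of -0.11 at percentile 2.84.

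Immediate early genes, which neurons induce with activity, had a ratio above 1 in 13 of 14 members over neurons, 7 with an interval above 1 and 7 with one that held 1, with a median log2 ratio of 0.25 at percentile 99.9. Fos had 5.53 and 10.6 CPM (1.91 [1.58 to 2.32]), Junb 10.6 and 17.6 CPM (1.65 [1.43 to 1.90]) and Bdnf, the neurotrophin gene, 25.1 and 35.0 CPM (1.40 [1.27 to 1.53]). Arc was at 0.852 [0.653 to 1.11]. In nuclei holding only Xist the median was 0.45. Heat shock and stress genes had a median of 0.08 at percentile 91.3, with 5 of 11 members lower. The rise of Fos was not confined to neurons, since its log2 ratio in oligodendrocytes was 1.19. There immediate early genes had a ratio above 1 in 5 of 9 members, 3 with an interval above 1 (median 0.09, percentile 88.05). In microglia 3 of 4 members were above 1 (median 0.15, percentile 73.7). Both glial medians lay inside the range of random lists, and neuronal activity was not tested.

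Receptor subunit genes were slightly lower over all neurons, and by more in several glial classes. GABA-A and glycine receptor subunits had a ratio below 1 in 15 of 17 members, 11 with an interval below 1 (median log2 ratio -0.11, percentile 0.84), with Gabra4 lowest at 0.742 [0.675 to 0.817]. Glutamate receptor subunits had one in 18 of 21 members, 12 with an interval below 1 (-0.14, percentile 0.04), among them the kainate receptor gene Grik2 at 0.809 [0.798 to 0.821]. In oligodendrocytes, astrocytes, oligodendrocyte precursors and microglia the medians were -0.19, -0.28, -0.24 and -0.32 for GABA-A and glycine receptor subunits (percentiles 10.0, 0.91, 1.91 and 0.83). For glutamate receptor subunits they were -0.37, -0.24, -0.11 and -0.63 (percentiles 0, 0.35, 8.55 and 0). The oligodendrocyte value of the former and the precursor value of the latter lay inside the range of random lists. Among itch circuit genes 13 of 18 had a ratio below 1, 5 with an interval below 1, with a median of -0.07 at percentile 13.8. Npy (51.3 and 29.9 CPM, 0.584 [0.537 to 0.634]), Gal (0.640 [0.572 to 0.715]), the dynorphin gene Pdyn (0.646 [0.527 to 0.789]) and the somatostatin receptor gene Sstr2 (0.704 [0.600 to 0.824]) were the lowest, while the gastrin-releasing peptide gene Grp was at 0.983 [0.901 to 1.07] and the enkephalin gene Penk at 1.23 [1.17 to 1.28].

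Dorsal inhibitory subtype genes had a ratio below 1 in 16 of 22 members over all neurons, with 14 intervals below and 4 above 1, a median log2 ratio of -0.16 at percentile 0.04, and 0.03 with clusters of equal weight. Dorsal excitatory subtype genes had a median of -0.04 at percentile 21.1, with 13 of 23 lower. Mitochondrial transcripts were lower in 10 of 10 members (median -0.77, percentile 0), with mt-Nd1 at 0.542 [0.528 to 0.557]. Nuclear-retained RNAs had a median of 0.14, inside the range of random lists (percentile 97.4), with 1 of 4 lower, Malat1 at a log2 ratio of 0.42 and Neat1 at -0.69. Myelin genes, free RNA in neurons, had a median of -0.16 (percentile 0.3) with 8 of 10 lower, and 0.03 after thinning. Reactive astrocyte genes had a median of -0.02 (4 of 7 lower, percentile 44.3) and activated microglia genes 0.14 (1 of 6 lower, percentile 74.6), both inside the range of random lists, and sex-linked genes -4.64 (4 of 6 lower, percentile 0).

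**Figure D3:**
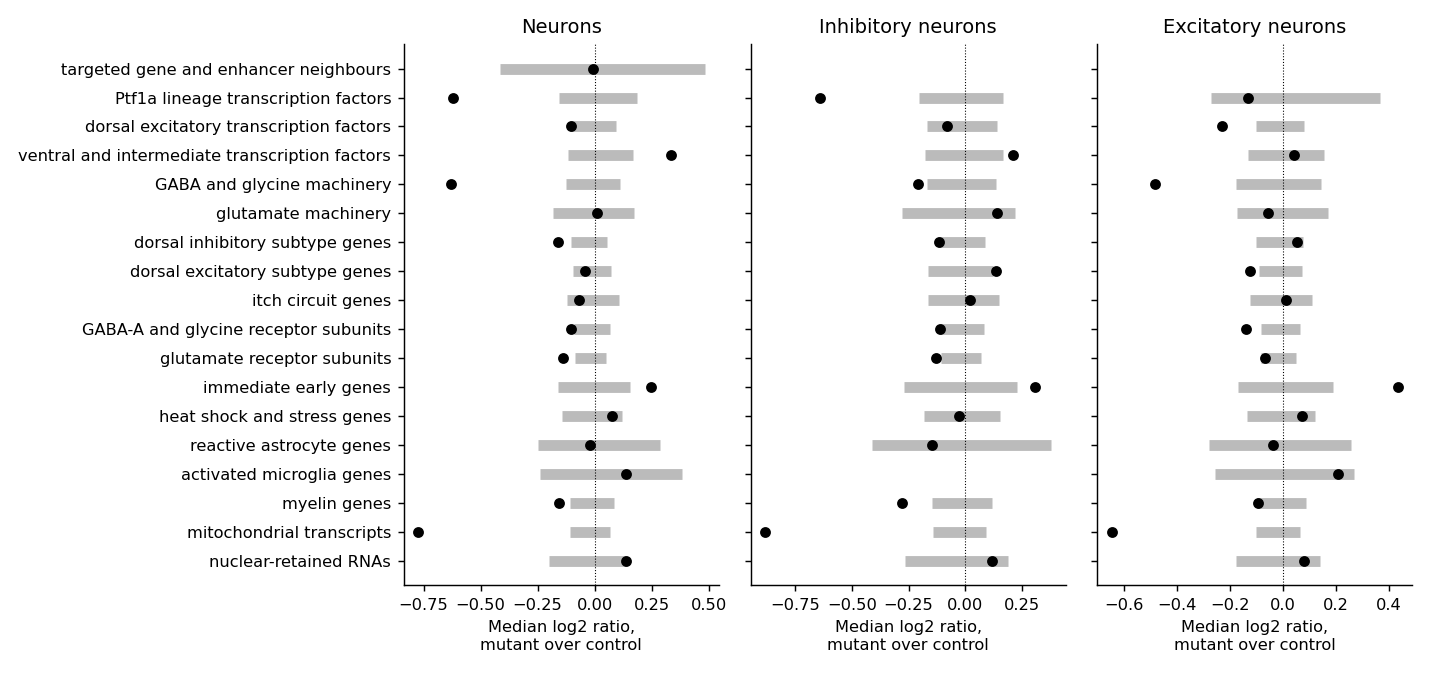
Points give the median log2 ratio (mutant over control) of each fixed gene list in all, inhibitory and excitatory neurons, and grey bars span the central 95% of 10000 matched random lists. In all neurons the Ptf1a lineage factors lie at -0.62 and the ventral factors at 0.33, and sex-linked genes are not drawn.

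Named genes of all neurons followed these groups in part. The largest ratios were those of S100a8 and S100a9, neutrophil calcium-binding proteins, with 4 and 114 and with 8 and 164 UMIs in the control and mutant libraries. Both were also higher in glia. The 164 mutant S100a9 UMIs were spread over 153 neurons, while the 16 mutant macrophage nuclei held 180. Free RNA may thus enter the values of both genes in neurons, which was not tested. Gem, a small GTP-binding protein gene, had 7.0 and 28.7 CPM (4.10 [3.52 to 4.78]), the corticotropin-releasing hormone gene Crh 1.43 and 5.61 CPM (3.92 [2.8 to 5.6]) and Acvr1c, an activin-type receptor gene, 5.80 and 17.9 CPM (3.08 [2.60 to 3.67]). Scrg1 (2.82), Itgad (3.98), M1ap (4.13), 4732419C18Rik (3.73) and Gm17201 (3.04) completed the 10 highest. Lowest was Igf2, a growth factor gene whose UMIs lay mostly in fibroblasts, with 102 control and 0 mutant UMIs, which allows up to 0.102 CPM against 3.32 CPM. Sall3 and Pax8 were among the 10 lowest, as were Shisa8 (38.6 and 18.6 CPM, 0.482 [0.435 to 0.534]), the immunoglobulin gene Ighm (0.285), Sftpb (0.264), the collagen gene Col1a2 (0.283), Igfbp2 (0.447) and Mgp (0.437), a leading gene of the excitatory cluster 16. Hba-a2 had a ratio of 0.406, but this haemoglobin gene shares reads with Hba-a1 and its value is uncertain.

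Within inhibitory neurons, the second gene comparison, the same lineage factors were lower as a fraction of the UMIs of that class. Cluster 1 held 607 of 1243 control and 522 of 767 mutant inhibitory nuclei, so the classes differ in makeup. Of 12 measured lineage factors 9 had a ratio below 1, 8 with an interval below 1, with a median log2 ratio of -0.64 at percentile 0. The median in oligodendrocytes, given above, was equally low. Gbx1 was at 0.555 [0.406 to 0.750], Tfap2b at 0.530 [0.371 to 0.745], Sall3 at 0.612 [0.526 to 0.711] and Pax8 at 0.656 [0.566 to 0.759], while Pax2 was at 0.876 [0.80 to 0.959]. Ventral factors had a ratio above 1 in 9 of 9 members, 5 with an interval above 1 (median 0.21, percentile 99.3), with Foxp2 at 60.6 and 94.1 CPM (1.55 [1.39 to 1.73]) and Nr5a2 at 2.31 [1.52 to 3.53]. Immediate early genes had one in 10 of 13 members, 4 with an interval above 1 (median 0.31, percentile 99.4).

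Subtype genes of dorsal inhibitory neurons had a ratio below 1 in 16 of 21 members within the class, 7 with an interval below and 5 with one above 1 (median log2 ratio -0.12, percentile 3.15). Pdyn had 12.8 and 4.43 CPM (0.346 [0.224 to 0.519]), Gal 49.0 and 25.4 CPM (0.517 [0.432 to 0.616]) and Rorb 255 and 150.3 CPM (0.590 [0.548 to 0.634]). Nppc, which encodes C-type natriuretic peptide, was at 0.610 [0.534 to 0.696]. Higher in the mutant library were Il1rapl2, 177 and 331 CPM (1.87 [1.76 to 1.99]), the neuronal nitric oxide synthase gene Nos1 (1.60 [1.31 to 1.97]), the RNA-editing family gene Adarb2 (1.31 [1.27 to 1.36]) and Penk (1.28 [1.16 to 1.40]). With each cluster weighted equally, the log2 ratio of Pdyn was 0.01, against its direction in the sum.

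Shares of inhibitory nuclei with a UMI were compared at equal depth, with 1 shallower nucleus left out per library. Rorb was detected in 15.1% [13.2 to 17.3] of control and 10.1% [8.02 to 12.4] of mutant inhibitory nuclei, against 1.34% and 1.28% of oligodendrocytes and 29% and 23.1% without thinning. Gal was detected in 4.03% [3.0 to 5.27] and 1.96% [1.10 to 3.21] (oligodendrocytes 0.498% and 0.611%, unthinned 10.3% and 6.65%). Cdh3 was detected in 3.22% and 1.44% (0.124% and 0.175%, unthinned 11.2% and 7.82%), a ratio of 0.446 [0.206 to 0.886]. Penk was detected in 6.84% and 10.2% (1.37% and 1.98%, unthinned 28.5% and 31.6%), a ratio of 1.49 [1.08 to 2.05]. Of 22 subtype genes, 18 lay above the oligodendrocyte share in the control library, 10 of them lower and 8 higher in the mutant library. Sst, Calb2 and Pvalb lay at or below that background and are read as free RNA.

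Among genes named by rule in inhibitory neurons, Gem had 4.06 and 25.7 CPM (6.33 [4.54 to 8.97]), with 22% of the mutant UMIs in 1 nucleus. Acvr1c (3.25), Scrg1 (2.45), Phkg1 (2.26), the metalloproteinase gene Pappa (2.21), the reelin gene Reln (2.06) and Il1rapl2 followed. The haemoglobin genes Hba-a1, Hbb-bs and Hbb-bt also ranked high, but 64.1%, 64.4% and 64.1% of their mutant UMIs came from 1 nucleus, and near-identical copies make them uncertain. The 10 lowest, with Pdyn, were the patched family gene Ptch2 (0.339 [0.196 to 0.559]), Pld1 (0.368), Shisa8 (66.5 and 29.6 CPM, 0.446 [0.379 to 0.522]), Cartpt (0.458, with 34.5% of mutant UMIs in 1 nucleus), Gsap (0.474), Hpse2 (0.490), Itm2c (0.540), Ankfn1 (0.550) and the zinc finger gene Zeb2 (0.553 [0.501 to 0.609]).

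Within excitatory neurons, the third gene comparison, transcription factors of the dorsal excitatory lineages had a ratio below 1 in 11 of 14 measured members, 9 with an interval below 1, with a median log2 ratio of -0.23 at percentile 0. Cluster 0, led by the ventral factors Zfhx3 and Pou6f2, held 480 of 2095 control and 676 of 2594 mutant excitatory nuclei, so this class also differs in makeup. The list of dorsal excitatory factors had a median of -0.30 in oligodendrocytes, 0.18 in astrocytes and -0.64 in microglia. Microglial Maf (184 and 206 CPM) and Mafb (91.1 and 103 CPM) stood higher than in excitatory neurons. Both were higher in the mutant library, so the low microglial median came from other members. In microglia 5 of 8 members had a ratio below 1, among them Ebf1 (0.408 [0.326 to 0.507]) and Ebf2 (0.312 [0.178 to 0.524]). Tlx3, which selects glutamatergic over GABAergic fate in dorsal horn neurons, had 29.6 and 18.9 CPM (0.640 [0.550 to 0.744]). Prrxl1 was at 0.779 [0.691 to 0.876], Maf at 0.764 [0.697 to 0.838] and Satb1 at 0.824 [0.770 to 0.882], while Lmx1b was at 1.06 [0.956 to 1.16]. At equal depth Tlx3 was detected in 3.92% and 2.82% of excitatory nuclei (0.591% and 0.727% of oligodendrocytes, unthinned 17.3% and 10.6%), with 1 control and 3 mutant nuclei left out. Immediate early genes had a ratio above 1 in 13 of 14 members, 7 with an interval above 1 (median 0.43, percentile 99.98), with Fos at 4.42 and 10.5 CPM (2.38 [1.78 to 3.22]) and Junb at 2.01 [1.64 to 2.48].

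Dorsal excitatory subtype genes had a ratio below 1 in 16 of 23 members within excitatory neurons, 10 with an interval below and 3 with one above 1 (median log2 ratio -0.12, percentile 0.31). The neurokinin B gene Tac2 was at 0.768 [0.737 to 0.80], the neurotensin gene Nts at 0.789 [0.757 to 0.823] and the cholecystokinin gene Cck at 0.844 [0.803 to 0.886]. Sst, the somatostatin gene, had 729 and 470 CPM (0.645 [0.626 to 0.664]) and Penk 131 and 172 CPM (1.32 [1.24 to 1.40]). With clusters of equal weight the list median was 0.04. At equal depth Penk was detected in 11% and 14% of excitatory nuclei (1.37% and 1.98% of oligodendrocytes, unthinned 30.8% and 35.1%). Tac1, the substance P gene, was detected in 15.6% and 18.6%, but its oligodendrocyte share also differed, 4.39% and 7.01% (unthinned 37.3% and 40.0%). Of 25 subtype genes, 23 lay above background in the control library, 14 of them lower and 9 higher in the mutant library.

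Genes named by rule in excitatory neurons again held S100a9 (5 and 113 UMIs, possibly free RNA as above), Gem (2.72 and 11.4 CPM, 4.2 [2.97 to 6.08]), Crh (2.24 and 9.36 CPM, 4.17 [2.85 to 6.29]), Itgad (6.13) and Scrg1 (3.03). The glycogen phosphorylase kinase gene Phkg1 (3.1 [2.47 to 3.92]), Abra (3.30), M1ap (3.44), 4732419C18Rik (3.32) and Gm17201 (3.0) were the other high ones. Lowest were Ighm (0.304), Hba-a2 (0.340, uncertain as above), Mgp (0.438), Gm14399 (0.434), Tmem215 (0.450), Gm12649 (0.474, with 31.1% of control UMIs in 1 nucleus), Vwa3b (0.485), 9330111N05Rik (0.506), Hmgcs1 and Sst. Hmgcs1, which encodes an early enzyme of cholesterol synthesis, had 116 and 70.2 CPM (0.605 [0.561 to 0.653]). For Gm12649 the log2 ratio was 0.35 with clusters of equal weight, against its direction in the sum.

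**Figure D4:**
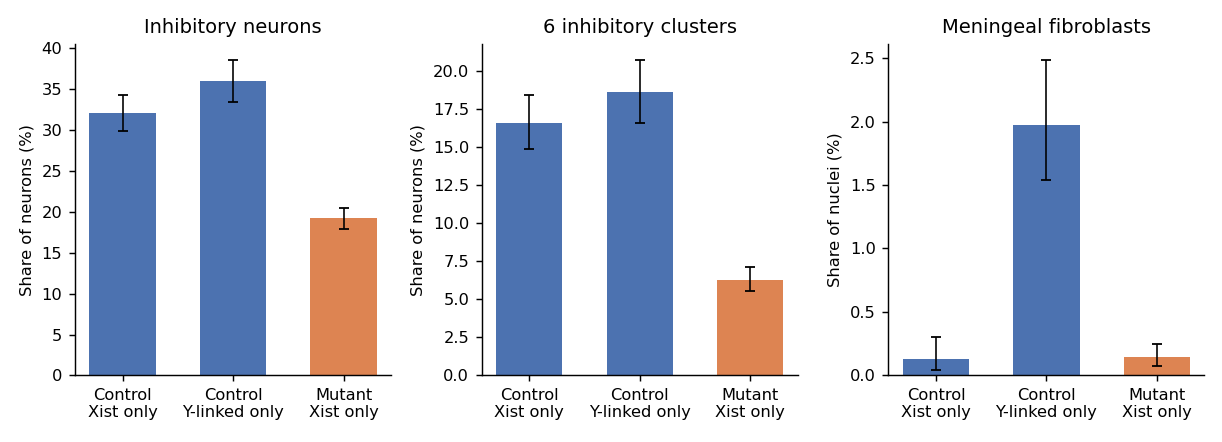
Bars give the share of neurons that are inhibitory, the share of neurons in the 6 lowered inhibitory clusters and the share of nuclei that are meningeal fibroblasts (percent, exact 95% counting intervals), for nuclei with Xist only or Y-linked UMIs only. The 6 clusters held 16.6% and 18.6% of control neurons and 6.29% of mutant neurons, while fibroblasts were 0.129%, 1.97% and 0.143%.

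In glial classes, the last comparison, S100a9 and S100a8 had the largest ratios in oligodendrocytes, at 48.6 [16.3 to 239] from 3 and 135 UMIs and 21.4 [8.87 to 67.4] from 5 and 99. Hif3a, a hypoxia-inducible factor gene, had 28.8 and 211 CPM in oligodendrocytes (7.31 [6.54 to 8.19]) and 17.7 and 97.3 CPM in oligodendrocyte precursors (5.50 [3.37 to 9.41]). Fkbp5, a co-chaperone gene induced by glucocorticoids, had 169 and 448 CPM in astrocytes (2.66 [2.34 to 3.02]), 351 and 1162 CPM in microglia (3.31 [2.92 to 3.76]) and a ratio of 3.1 [2.54 to 3.81] in oligodendrocyte precursors, where Errfi1 was at 3.42 [2.57 to 4.61]. Fkbp5 and Hif3a also differed within the control library. In oligodendrocytes, of which cluster 0 held 44.9% in control nuclei with Xist only, 16.3% with Y-linked UMIs only and 50.1% in mutant nuclei with Xist only, Fkbp5 had 237 CPM in control nuclei with Xist only, 54.9 CPM in control nuclei with Y-linked UMIs only and 553 CPM in mutant nuclei with Xist only, and Hif3a had 57.1, 4.27 and 214 CPM. In the same groups of oligodendrocytes Errfi1 followed this order, at 124.8, 73.92 and 301.6 CPM, as did Plin4, at 9.082, 1.955 and 28.06 CPM. Ddit4 had 36.8 [31.4 to 42.7], 31.5 [27 to 36.4] and 105 CPM there, with control intervals that overlap. The order was not followed by Hr in oligodendrocytes, at 5.41, 10.1 and 8.44 CPM. Nor was it by Errfi1 in oligodendrocyte precursors, at 54.2, 56.0 and 198 CPM. The astrocyte gene Hr, a nuclear receptor corepressor, was at 3.18 [2.46 to 4.14], and A830008E24Rik at 4.11. Astrocyte clusters also differ between the libraries, as given above.

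Lowest in oligodendrocytes, whose clusters differ between the libraries as given above, were the laminin gene Lama2, with 162 and 43.6 CPM (0.269 [0.244 to 0.297]), Fcho1 (0.155 [0.109 to 0.215]) and Mpz, the Schwann cell myelin gene, of which 80.9% of control UMIs came from 1 nucleus. In astrocytes the dicarboxylate transporter gene Slc13a3 (0.292 [0.20 to 0.420]), Gpr158 (0.385 [0.330 to 0.448]) and RP23-216D14.3 (0.203) were lowest. In oligodendrocyte precursors these were Pola1 (0.446), Prickle2 (0.528) and RP24-274B19.1 (0.454). In microglia Ptgds (2.43) and Scrg1 (3.14) were high, and Gm28928 (47.6% of control UMIs in 1 nucleus), Hs3st4 (27.6%) and Ptprt (19.9%) were low.

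Of the lists that fit glia, heat shock and stress genes had a ratio above 1 in 9 of 11 members in oligodendrocytes, a class of different makeup, with 6 intervals above 1 (median log2 ratio 0.28, percentile 99.9), led by Ddit4, a stress-induced inhibitor of mTOR signalling, with 33.1 and 103 CPM (3.11 [2.78 to 3.49]). Myelin genes had a median of -0.14 at percentile 17.4, with 8 of 10 below 1 (7 intervals below 1) and Opalin lowest at 0.539 [0.508 to 0.572]. Reactive astrocyte genes in astrocytes had a median of 0.08 at percentile 82.9, with Gfap at 1.23 [1.09 to 1.39]. Activated microglia genes in microglia had a median of -0.13 at percentile 27.5, with the lysosomal gene Cd68 at 0.436 [0.285 to 0.653] and Apoe at 1.58 [1.45 to 1.73]. Mitochondrial transcripts were lower in 10 of 10 members in each glial class. Their medians were -0.44 in oligodendrocytes (percentile 0.01), -0.40 in astrocytes and -0.39 in oligodendrocyte precursors (both percentile 0), and -0.22 in microglia (percentile 4.73).

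**Figure D5:**
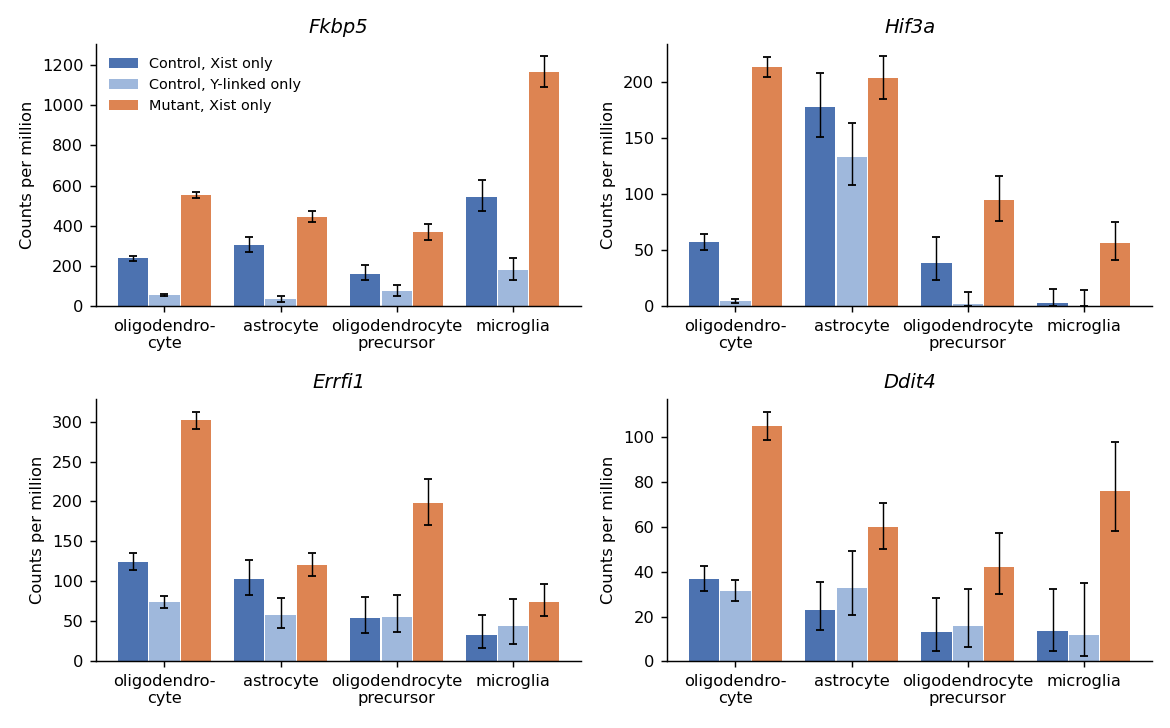
Bars give CPM (exact 95% intervals) of Fkbp5, Hif3a, Errfi1 and Ddit4 in 4 glial classes, for control nuclei with Xist only, control nuclei with Y-linked UMIs only and mutant nuclei with Xist only. In oligodendrocytes Fkbp5 stood at 237, 54.9 and 553.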

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

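Chosen only after the results were seen were the tests on nuclei with an Xist UMI and no Y-linked UMI only, the clustering of unresolved neurons on their own, the calls from at least 2 UMIs, and cluster shares with all fixed marker genes left out. No paired analysis was possible because each genotype had 1 library. Of 1393 alternative values, those that stayed within the counting interval of the main value were 102 of 112 class shares, 19 of 42 shares of inhibitory or excitatory neurons or their ratio, 71 of 77 cluster shares, 322 of 378 list medians, 280 of 353 named genes and 414 of 424 shares of nuclei with a UMI. For list medians a band as wide as the range of random lists, centred on the main value, took the place of that interval. Where the main interval held 1, a value inside it could lie on the other side of 1. Of 60 named genes of neurons, 58 kept their direction with clusters of equal weight and all 60 under the other settings, and 41 were still named when at least 200 UMIs were asked for. Scaling by TMM factors or by totals without Malat1 and mitochondrial genes took no list median outside its band and no named gene outside its interval. Some class shares could not be given because no cluster took the name, among them fibroblasts at resolution 2 and at most 1% mitochondrial UMIs.

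Every alternative kept the share of neurons that are inhibitory lower and the share of neurons that are excitatory higher in the mutant library, but the size moved. Beside 0.575 for the share and 0.498 for the ratio of inhibitory to excitatory neurons, a minimum of 200 genes gave 0.676 and 0.575, a minimum of 1000 genes 0.672 and 0.561, at most 1% mitochondrial UMIs 0.691 and 0.585, and doublet calls kept 0.686 and 0.580. A resolution of 0.5 gave 0.694 and 0.594, a resolution of 2 gave 0.691 and 0.589, and 50 principal components gave 0.685 and 0.582. Neurons called one by one, thinned to 1000 UMIs, gave 0.678 and 0.604, and neurons called one by one from at least 2 UMIs gave 0.581 and 0.390, with an excitatory share ratio of 1.49. Unresolved neurons clustered on their own and called by the same rule gave 0.696 and 0.594, by construction, since their inhibitory parts held more mutant than control nuclei. With all fixed marker genes left out of the variable genes the values were 0.366 and 0.353, and the excitatory share ratio was 1.04. The same setting reversed the shares of neurons of the clusters matched to cluster 0 (0.860) and to cluster 1 (1.41). Each new cluster was matched to the former cluster that gave it the most nuclei. Matched clusters hold other sets of nuclei, so the reversal need not be one of the same nuclei. The clusters matched to the 6 lowered ones had 0.354, close to the 0.366 of all inhibitory neurons in this setting. Outside the unresolved neurons the cause was not tested.

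Among class shares of nuclei, the neuron ratio was 0.919 at most 1% mitochondrial UMIs and 0.912 in nuclei with Xist only. The share of nuclei unnamed was reversed with a minimum of 1000 genes (1.15), at most 1% mitochondrial UMIs (1.30) and Xist only (1.32), and that of meningeal fibroblast nuclei with Xist only (1.11). The fibroblast share of control nuclei with Xist only was 0.0653 [0.0206 to 0.160] times that with Y-linked UMIs only. The Xist-only setting thus keeps 5 of the 114 control fibroblast nuclei. For the other shares the cause was not tested.

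For log2 medians of lists, the mean over clusters of equal weight, which takes cluster shares out by construction, gave -0.14 for Ptf1a lineage transcription factors (dI4 and dILA) in neurons and -0.32 for GABA and glycine machinery in neurons. It reversed dorsal inhibitory subtype genes in neurons (0.028), dorsal excitatory subtype genes in excitatory neurons (0.043), Pdyn in inhibitory neurons (0.0075) and Gm12649 in excitatory neurons (0.35). Every nucleus thinned to 1000 UMIs gave -0.94 for the lineage factors and 0.030 for myelin genes in neurons, reversed. Doublet calls kept gave -0.051 for dorsal excitatory subtype genes in inhibitory neurons, reversed. Nuclei with Xist only gave 0.45 for immediate early genes in neurons, and 0.11 and 0.25 for sex-linked genes in neurons and sex-linked genes in excitatory neurons, reversed by construction, since Y-linked UMIs were taken out. For the thinned, doublet and immediate early gene values the cause was not tested.

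Depth set further limits. Ptf1a, at 0 and 1 UMIs, could not be compared, and the 13 fibroblast and 16 macrophage nuclei of the mutant library allow no account of genes within those classes.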

Other observations

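The tests of sex mix, of dorsal tissue and of clustering as origins of the lower inhibitory share were chosen only after the result was seen, as were the calls from at least 2 UMIs, the leaving out of a dorsal cluster led by ventral factors, the rule naming genes over all nuclei and the lists of glucocorticoid-induced, neutrophil and Schwann cell genes. Over all nuclei, the 5 genes ranked highest were Lcn2, S100a9, Retnlg, S100a8 and Scgb3a1. Lcn2, which encodes the iron-binding acute-phase protein lipocalin-2 (ENSMUSG00000026822), had 3 control and 306 mutant UMIs, a ratio of 106 [36.1 to 519]. Of the mutant UMIs, 64.7% lay in endothelial cells, where the control library had 0, and 30.7% in a single nucleus. Scgb3a1, a secretoglobin gene, had 7 and 129 UMIs (19.2 [9.07 to 48.8]), of which 3 and 87 were in endothelial cells. Retnlg, a resistin-family gene of neutrophils, had 3 and 150 UMIs (52.2 [17.5 to 256]), with 48.0% of the mutant UMIs in macrophages. S100a9 had 21 and 593 UMIs (29.5 [19.1 to 48.0]) and S100a8 14 and 365 (27.2 [16.0 to 50.2]). Macrophages held 30.4% of the mutant S100a9 UMIs, and neurons and oligodendrocytes held 164 and 135 of them. The neutrophil genes not looked at before had a median log2 ratio of 0.41, at percentile 98.0, with intervals above 1 for Ngp, Camp and Cxcr2 and intervals that held 1 for the other 3 measured members. Within nuclei holding only Xist, S100a9 had 0.527 CPM in the control and 9.20 CPM in the mutant library.

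Among the genes ranked lowest, Igf2 had 866 control and 40 mutant UMIs (0.0482 [0.0342 to 0.0662]), with 66.4% of the control UMIs in fibroblasts, and Col3a1 had 636 and 35 (0.0574 [0.0396 to 0.0807]). Iigp1, an interferon-induced GTPase gene, had 418 and 4 UMIs (0.00998 [0.00271 to 0.0258]), with 81.6% of the control UMIs in fibroblasts. Gbp2, another interferon-induced GTPase gene, had 106 and 11 (0.108 [0.0525 to 0.202]), with 47.2% of the control UMIs in fibroblasts. In the control library Iigp1 had 1.58 CPM in nuclei with Xist only and 12 CPM in nuclei with Y-linked UMIs only, and Igf2 6.38 and 22.5 CPM. Mpz had 209 and 6 UMIs, but 70.8% of the control UMIs came from 1 nucleus. The remaining genes of the 10 highest were Matn1 (8.20), 1700071M16Rik (8.41), Plin4 (4.30), Hif3a (4.23) and Itgad (4.24), the last 2 with 69.3% and 79.4% of their mutant UMIs in oligodendrocytes, and of the 10 lowest Fmod (0.0952), Prdm6 (0.115), Col1a1 (0.159), Slc47a1 (0.134) and Lum (0.118).

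For the lower share of inhibitory neurons, a different sex mix as the whole origin is argued against by nuclei holding only Xist, where the ratio of inhibitory to excitatory neurons, mutant over control, was 0.538 with an upper bound of 0.615. Within the control library the same ratio, nuclei with Xist only over those with Y-linked UMIs only, was 0.806 [0.690 to 0.941]. The measure thus also differed within 1 genotype, in the same direction, so sex or single animals as part of the origin stay open. The 13 dorsal excitatory clusters, with a share ratio of 1.15 (lower bound 1.09), argue against less dorsal tissue as the whole origin. The ratio was 1.10 [1.03 to 1.18] for the 12 without cluster 0, which ventral factors lead. These are shares of all neurons, and every other share rises when inhibitory neurons fall. The 12 stood below all excitatory neurons (1.15) and cluster 0 (1.31), so a fall relative to other neurons is not excluded. The ventral factors (percentile 99.95) and dorsal excitatory factors (percentile 2.84) over neurons go the way that less dorsal tissue would take them, so a smaller difference in dissection stays open. For joint clustering, neurons called one by one had an upper bound of 0.707. They were themselves picked by that clustering, and free RNA alone gave 0.657 in oligodendrocytes, so these calls cannot decide it. Calls from at least 2 UMIs over all nuclei, which use no clusters, gave 0.414 [0.299 to 0.574]. They called 398 control and 239 mutant nuclei inhibitory, of which 294 and 183 were named neurons. Oligodendrocytes went the same way, with 30 and 19 inhibitory and 2 and 6 excitatory calls, so free RNA is not excluded here either. The difference was thus seen without clusters, but these calls cannot separate it from free RNA. The enhancer mutation and differences between the few animals or preparations stay open, and no test here separates them, since each genotype had 1 library.

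Most glucocorticoid-induced genes not looked at before had ratios above 1 in glia of the mutant library, with median log2 ratios of 0.98 in oligodendrocytes (12 of 13), 0.58 in astrocytes (12 of 13), 0.83 in oligodendrocyte precursors (7 of 7) and 1.09 in microglia (9 of 9). Exceptions were Tsc22d3 in oligodendrocytes (0.904 [0.856 to 0.955]) and Per1 in astrocytes (0.881 [0.645 to 1.21]), and the lowest percentile of the 4 medians was 100, so a glucocorticoid response beyond the first genes is a candidate explanation. Single animals, or their sexes, could also differ in it: within the control library, the oligodendrocytes with Xist only, 44.9% of them in cluster 0, had ratios above 1 to those with Y-linked UMIs only (16.3%) in 12 of 12 measured genes, by 0.672 of the size of the difference between libraries (median log2 ratio 0.66). The same comparison gave 0.39 in astrocytes (7 of 9 genes above 0, percentile 99.9), 0.39 in oligodendrocyte precursors (2 of 4, percentile 99.4) and -0.06 in microglia (1 of 3, percentile 35.7), although Fkbp5, outside this list, had 545 and 180 CPM in control microglia, and Ddit4, also outside it, only 36.8 and 31.5 CPM in control oligodendrocytes. Among nuclei with Xist only the libraries still differed by 0.76 in oligodendrocytes, and handling, time of day and genotype were not tested.

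Fewer fibroblast nuclei in the mutant library may come from 1 control animal. The fibroblast share of control nuclei with Xist only was 0.0653 [0.0206 to 0.160] times that of control nuclei with Y-linked UMIs only, and the share in mutant nuclei with Xist only, 0.143%, lay close to the 0.129% of the former. Less meninges and nerve root in the dissected mutant tissue cannot be told apart from this. Schwann cell markers other than Mpz had a median log2 ratio of 0.048 with 4 of 6 ratios above 1, inside the range of random lists from -0.25 to 0.24. This median cannot decide it, since no cluster was named Schwann cell. Cdh19 was a leading gene of the mixed clusters 9 and 22, which held oligodendrocyte markers, and Scn7a of neuron cluster 18. No biological explanation was tested.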
